A study of Canis lupus familiaris with 20 samples.

How the data were processed

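Epiphyseal cartilage from the cranial and caudal ends of the T12 vertebra was pooled per animal, from 20 dogs in 4 groups of 5: heterozygous control and homozygous MPS VII dogs at postnatal day 9 and day 14. Polyadenylated RNA was sequenced with a stranded mRNA kit in paired 100-base reads on an Illumina HiSeq, per the labels' protocols. The reads were mapped to the dog genome CanFam3.1 with Ensembl build 77, per the labels' protocols. The submitters' processing notes name CASAVA 1.8.2, bcl2fastq, STAR 2.4.0j, HTSeq and edgeR, without the role or order of each. The strand setting of the counting and the treatment of reads that match several genes are not given in the sources used here, so values of overlapping genes, antisense genes and near-identical copies are uncertain.

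The deposited table holds raw counts per gene for 24580 Ensembl genes in 20 libraries, with the exon positions, strand and summed exon length of each gene, per the file headers. Each column name matched the title of 1 sample, and 0 count columns belonged to no sample. Of counts under 200 above 0, 65.2% to 76.4% per library were even numbers. Counts would be even where both mates of a pair were counted singly, so fits were repeated with all counts halved. Counting error would then be understated by intervals that treat each count as independent. The depth per library was 15772761 to 28028365 counts. PCR copies cannot be told apart from molecules, so lower bounds on folds cover counting error only. These bounds set a group with 0 counts at a floor of 3 counts over the whole group, and were repeated on halved counts with the same floor.

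Each library was taken as a separate animal from its label. No pair of libraries of 1 group held counts alike within sampling noise, as copies of 1 library would (chi-square per gene 16.7 to 607 over 40 pairs, genes with at least 20 counts).

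Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the 4 groups, which left 14550 genes and dropped 10030 genes with 0.0413% of all counts. Libraries were scaled by the trimmed mean of M values (TMM). A single fit with 1 mean per group over all 20 libraries (estimateDisp, glmQLFit with robust estimation, glmQLFTest) gave the 5 comparisons: genotype at each age, age in each genotype, and the difference of the age change between genotypes. P-values were adjusted by Benjamini and Hochberg over all tested genes, with a threshold of 0.05. The biological coefficient of variation was 0.239. Standard errors of log2 fold changes are the fold change divided by the square root of the F statistic. CPM are the normalised counts that edgeR's cpm function gives from the TMM-scaled library sizes, and log2 CPM for components used a prior count of 2. Values per library (totals, shares of the most abundant genes, mitochondrial share, share of even counts) were compared between groups by exact two-sided permutation tests, 20 in all.

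The rule for the genes named in the text took, per comparison, those past the threshold with the largest log2 fold change in each direction whose libraries do not overlap between groups and whose mean is at least 2 CPM in the higher group, and for the difference of the age change those with the smallest p. It was written for genes with a symbol. Of the identifiers, 0 matched the symbol table used here, which is for another assembly, UU_Cfam_GSD. The rule was therefore applied without symbols, to at most 2 genes per direction and comparison, and identifiers are printed for 4 genes. For the same reason 27 gene lists of cell types and pathways fixed before the data were examined, and the level of GUSB, were not tested. In their place 6 groups that the table itself defines were tested, chosen after the table was seen: the mitochondrial chromosome, the X chromosome, single-exon genes, genes with under 300 and over 5000 bases of exon, and the 20 most abundant genes. They were tested with camera (limma 3.58.1, preset correlation 0.01, adjusted over the 6 groups of a comparison, and again with an estimated correlation). Runs of at least 3 neighbouring tested genes called the same way with at least 2-fold changes were counted and set against 1000 random orders of the genes; this too was chosen after the table was seen. The genes named inside runs were chosen after their values were seen.

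Of the genes called with age in controls, the share with the same sign in affected dogs was computed with the fry test per direction. The size of the age change was compared in genes picked with 3 against 3 control libraries and measured in the held-out controls and in the affected libraries, over 100 choices.

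The edgeR test and the held-out ratio were tested on simulated counts for the 14550 genes with 200 genes changed by known folds. At 1.5-fold, 2-fold and 4-fold the test recovered 23.9%, 59.7% and 87.9% of changed genes for genotype at day 9, 28.4%, 71.6% and 86.4% for genotype at day 14, 35.8%, 68.7% and 87.9% for age in controls, 25.4%, 59.7% and 89.4% for age in affected dogs, and 7.46%, 38.8% and 72.7% for the difference. Between 3.12% and 5.88% of the calls were false. The simulated counts held no library far from its group and no trend on exon length, and only these 200 genes changed. The rates of recovered and false calls therefore need not hold for the real data. The held-out ratio came out at 1.04 and 1.01 where both genotypes were simulated with the same change, and at 0.00580 and -0.00728 where only controls changed.

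Alternatives fixed before the data were examined were median-ratio (RLE) and upper-quartile scaling, no filter, a stricter filter (over 1 CPM in at least 5 libraries), the DESeq2 1.42.0 Wald test, fits of only the groups compared, fits without robust estimation, 1 surrogate variable (sva 3.50.0), a 2-fold threshold, and leaving out each library in turn. Alternatives chosen after the data were seen were halved counts, the removal of each library's trend on exon length, the settings for the gene groups, runs and shared calls, and the held-out ratios without affected day 9 replicate 3. Litters were matched between genotypes per the labels, but no litter, sex or batch of a sample was used here, and replicate numbers only name the animals.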

Results

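Gene expression was measured by RNA sequencing in epiphyseal cartilage of the T12 vertebra of young dogs. Mucopolysaccharidosis VII (MPS VII) is an inherited lysosomal storage disease in which glycosaminoglycans are not fully broken down, and the dogs were of a naturally occurring model of it that carries a missense change in the GUSB gene. Affected dogs were homozygous for the change and control dogs were heterozygous. There were 5 control and 5 affected animals at postnatal day 9, and 5 control and 5 affected animals at postnatal day 14, each animal giving 1 library. The series addressed how the cartilage of affected animals differs at ages around the start of bone formation in the epiphysis. Total counts per library ran from 15772761 to 28028365. The day 9 libraries held 21419930 to 28028365 counts and the day 14 libraries 15772761 to 22471728, so age and depth went together. In controls the mean fell from 26163600 ± 2080570 (SD, n = 5) to 18458600 ± 1557530 (SD, n = 5), with an exact two-sided permutation p of 0.00794, the smallest that 5 against 5 allows, and an adjusted p of 0.0397 over 20 such tests. In affected dogs the means were 24272300 ± 2016110 and 19121800 ± 2443460, with an exact permutation p of 0.0159 and an adjusted p of 0.0635. Genes are given by their position in CanFam3.1, and by their Ensembl identifier for 4 of them, since the file used here does not pair identifiers with gene names.

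The libraries separated by group on principal components of log2 CPM (normalised read counts, scaled to the size of the library). On the first component, with 31.3% of the variance, the 5 control libraries of day 14 lay between -75.4 and -53.7, and the other 15 libraries between -6.87 and 55.2. On the second, with 19.1%, the control libraries of day 9 lay at 40.9 to 50.8 and the affected libraries of day 14 at -48.6 to -24.4, while affected day 9 replicate 3 was lowest at -55.6, against -2.53 to 9.96 in the rest of its group. The third, with 11.4%, set the same library at 85.0 against -17.8 to -4.70 in the rest of its group.

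**Figure D1:**
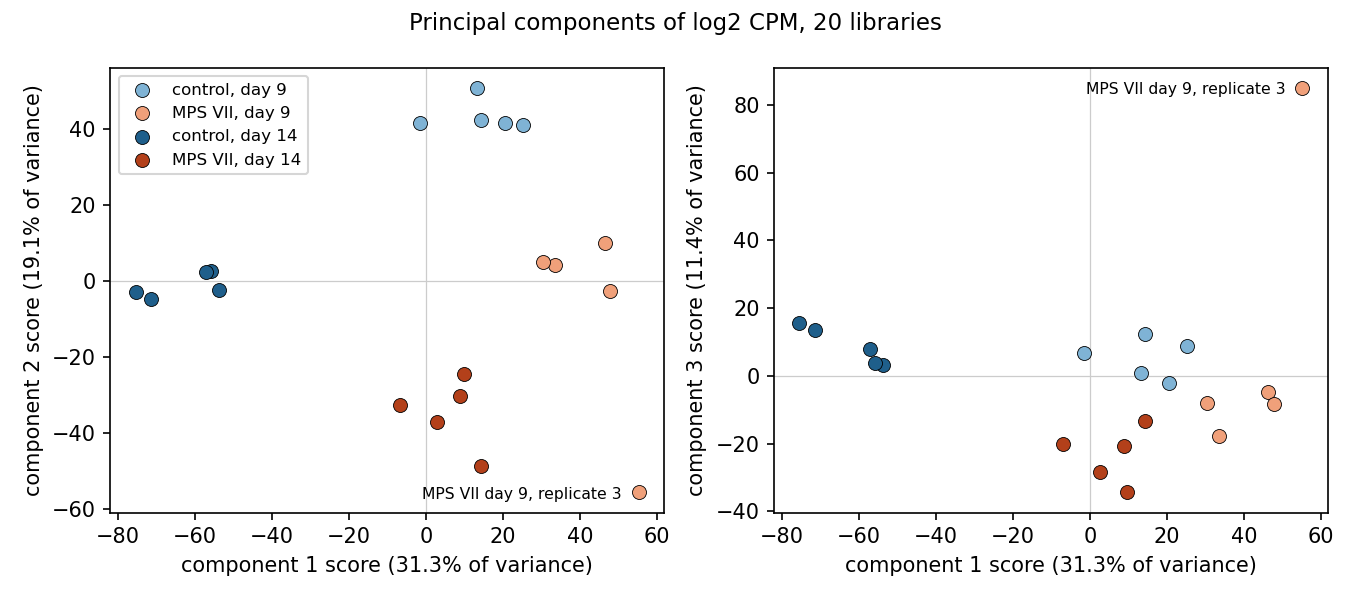
Scores of the 20 libraries on principal components 1 and 2 (left) and 1 and 3 (right) of log2 CPM, with 1 point per animal coloured by group and the share of variance on each axis. The control libraries of day 14 sit at -75.4 to -53.7 on component 1, and replicate 3 of the affected day 9 group sits at 85.0 on component 3.

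The first comparison asked how the cartilage of affected dogs differed from that of controls at day 9. The gene ENSCAFG00000002753, on chromosome 14 from 36918913 to 36947518, rose from 2.31 CPM ± 1.31 in controls to 303 CPM ± 69.2 in affected dogs (SD, n = 5 each), a log2 fold change of 7.05 ± 0.42 (SE, adjusted p = 2.99e-09 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The gene ENSCAFG00000019945, on chromosome 9 from 53425168 to 53472725, rose by 6.65 ± 0.98 on the log2 scale, although replicate 3 of the affected dogs held 298 CPM against 14.9 to 28.7 CPM in the rest of its group; controls stood at 0.7505 CPM ± 0.301. Without that library the log2 fold change was 4.77 and kept its call. The gene ENSCAFG00000017319, on chromosome 20 from 49813686 to 49817040, fell from 804 CPM ± 332 to 57.4 CPM ± 30.1, with a log2 fold change of -3.81 ± 0.39 (edgeR adjusted p = 1.61e-06). The gene ENSCAFG00000015404, on chromosome 27 from 41108016 to 41217919, fell from 2.73 CPM ± 1.28 to 0.206 CPM ± 0.0837, with a log2 fold change of -3.68 ± 0.43. The rule that picked these 4 genes required all 5 libraries of one genotype to lie outside the range of the other.

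Runs of at least 3 neighbouring tested genes that all rose at least 2-fold in affected dogs of day 9 were found at 7 places, and no run fell. Randomly reordered genes gave 0.490 runs on average and 4 at most in 1000 reorderings, so the permutation p of 0.001 is the smallest they can give. On chromosome 11, 5 genes between 67678600 and 67746324 rose by 1.61 to 6.37 on the log2 scale. The strongest of them, starting at 67713589, went from 0.0489 CPM ± 0.0453 to 4.75 CPM ± 3.26, and its neighbour starting at 67741492 from 5.38 CPM ± 0.761 to 16.5 CPM ± 3.57. On chromosome 12, 4 genes between 9914891 and 10000216 rose by 1.04 to 4.28, and the gene starting at 9923301 reached 12.5 CPM ± 1.42 from 0.635 CPM ± 0.195. On chromosome 9, 4 genes between 5858852 and 5976435 rose by 2.06 to 3.50. Neighbouring genes can be near-identical copies whose reads are shared, so the count of genes within a run is less certain than the change of the run. The run on chromosome 18 from 51767750 held 3 genes within 0.846 kb, which need not be separate changes. The number of runs was 4 without control day 9 replicate 2, 3 or 5 and without affected day 9 replicate 3.

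In all, 1220 of 14550 tested genes (8.38%) differed between genotypes at day 9 (edgeR quasi-likelihood test, adjusted p under 0.05), 899 higher and 321 lower in affected dogs. Of these, 482 rose and 126 fell at least 2-fold. The libraries of both genotypes did not overlap in 1177 of all tested genes (8.09%, where chance gives 0.794%), among them 856 of the called ones. None of the 17 tested mitochondrial genes passed the test at day 9 (median log2 fold change -0.15). Of 555 X-chromosomal genes 30 rose and 19 fell, and camera, which compares a group with all other genes, gave an adjusted p of 0.562. At day 14, 90 of them rose and 37 fell (median 0.12, camera adjusted p = 0.222). The sex of the animals was not used in the fits. A different mix of sexes between the groups therefore cannot be told apart from genotype in these values. With only the day 9 libraries in the fit, 711 genes passed.

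At day 14 the same comparison was made in the older animals. The gene ENSCAFG00000002753 again rose, to 815 CPM ± 201 in affected dogs against 9.24 CPM ± 4.91 in controls, a log2 fold change of 6.46 ± 0.40 (edgeR adjusted p = 4.73e-09). The gene ENSCAFG00000017319 stood at 2303 CPM ± 316 in controls and 57.6 CPM ± 28.9 in affected dogs, a log2 fold change of -5.32 ± 0.42. On chromosome 5, a gene from 55782140 to 55828330 rose by 5.45 ± 0.39 on the log2 scale, from 0.405 CPM ± 0.214 to 18.1 CPM ± 6.11 (SD, n = 5 each). On chromosome 4, a gene from 57934459 to 57958154 held 675 counts over the 5 control libraries and 0 over the 5 affected ones. It was at least 209-fold lower in affected dogs, against a floor of 3 counts over the group, or at least 104.2-fold with all counts halved, in case both mates of a pair were counted. On chromosome 7, a gene from 19498755 to 19514228 held 266 counts over the control libraries and 0 over the affected ones, at least 82.5-fold lower (40.6-fold with counts halved); its level in controls was 2.41 CPM ± 2.17. Control day 14 replicate 4 held 127 of the 266 counts, and without it the fitted log2 fold change went from -8.72 to -8.09 and kept its call.

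Neighbouring genes moved together at 17 places at day 14, with 13 runs higher and 4 lower in affected dogs, against 2.11 on average and 8 at most in reordered genes (permutation p = 0.001, the smallest possible). Some runs were of 3 genes within a short stretch, such as 1.08 kb on chromosome 18 from 46206173 and 1.4 kb on chromosome 5 from 11294895. Reordering treats each gene as independent, so the genes of such runs need not be separate changes. The largest fall was on chromosome 32, where 3 genes between 11051535 and 11362391 fell by 2.25 to 5.39 on the log2 scale. They stood at 159 CPM ± 108.4, 3055 CPM ± 1244 and 5776 CPM ± 1835 in controls, and at 3.82 CPM ± 1.83, 122 CPM ± 47.4 and 1215 CPM ± 337 in affected dogs. The run on chromosome 12, from 9858317 to 10000216, held 5 genes that rose by 1.35 to 3.58. The run on chromosome 9, from 5858852 to 5976435, rose by 1.00 to 2.66, and 3 genes of the run on chromosome 11, from 67713589 to 67746324, rose by 1.395 to 4.64. The number of runs fell to 11 without control day 14 replicate 1, and to 8 without control day 14 replicate 4 or affected day 14 replicate 4.

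At day 14, 3202 genes (22.0%) differed between genotypes, 1640 higher and 1562 lower in affected dogs, by the same edgeR test. At least 2-fold changes were found in 644 that rose and 573 that fell. Libraries of both genotypes did not overlap in 2779 of all tested genes (19.1%), among them 2290 of the called ones. Of the 20 most abundant genes 5 rose and 2 fell, with a camera adjusted p of 0.222.

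Genes that differed between genotypes at day 9 largely differed the same way at day 14. Both ages called 534 genes higher and 185 lower in affected dogs, where independent lists would share 101.3 and 34.5; 5 genes were called in opposite directions. Across all 14550 genes the log2 fold changes at both ages correlated with a Pearson r of 0.551 and a Spearman rho of 0.420. This is across genes, which are not independent replicates, and no library entered both comparisons. The gene ENSCAFG00000015404 was among those lower at both ages (log2 fold change -2.56 ± 0.39 at day 14), and ENSCAFG00000019945 among those higher (5.31 ± 0.99, and 4.60 without affected day 14 replicate 4).

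**Figure D2:**
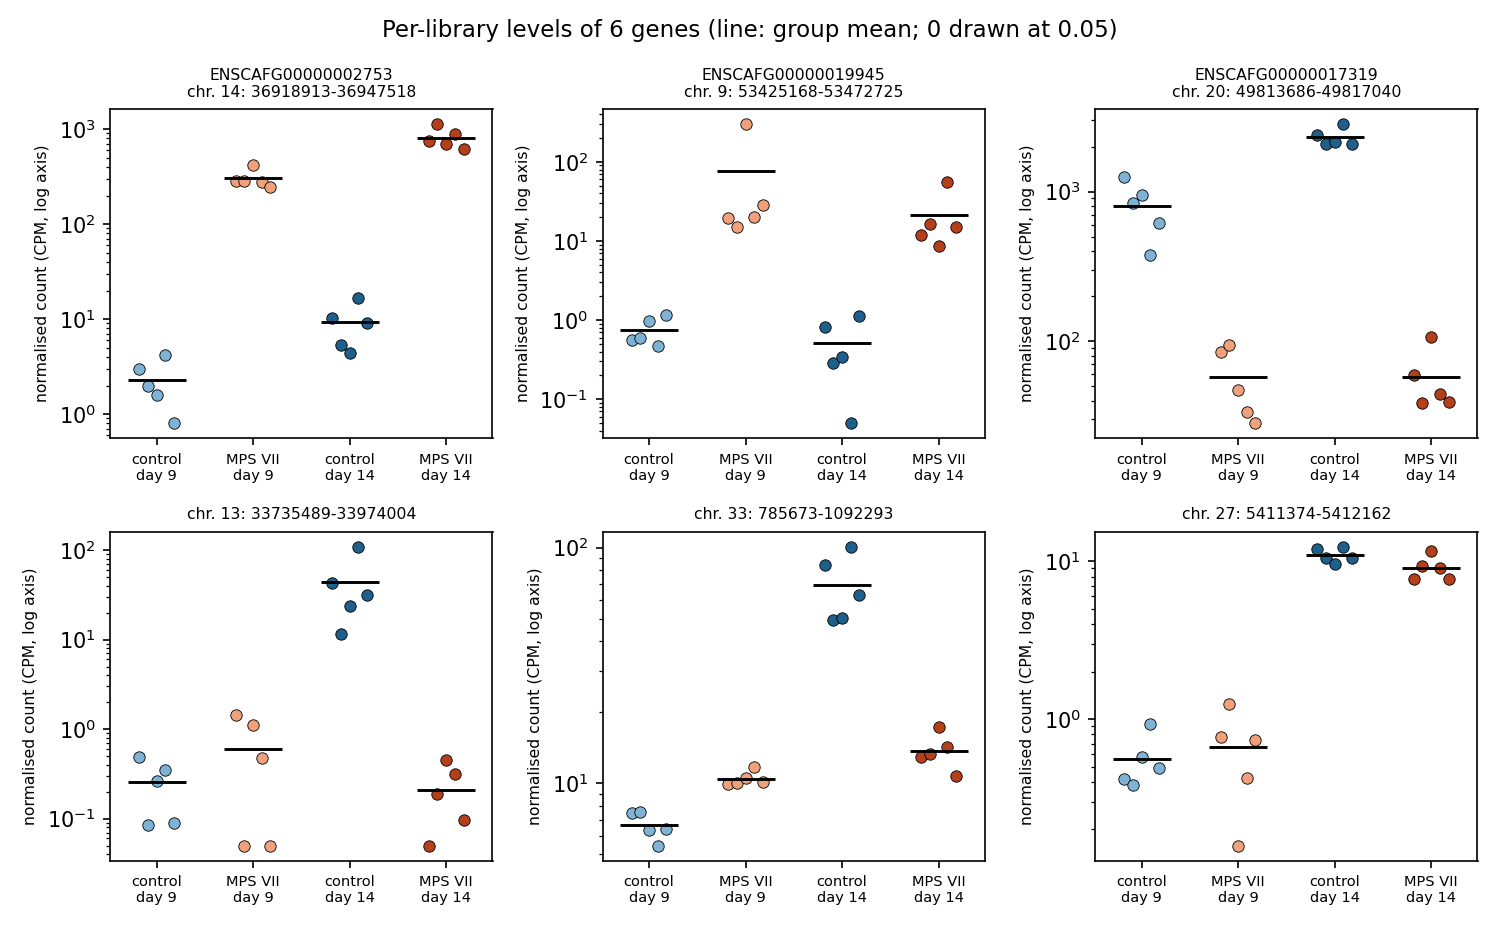
CPM per library (points, log axis, 5 animals per group) and group mean (line) of 6 genes named by position and, for 3 of them, by identifier; libraries at 0 are drawn at 0.05. The genes on chromosomes 14, 9 and 20 separate the genotypes at both ages, those on chromosomes 13 and 33 stand highest in control dogs of day 14, and that on chromosome 27 rises with age in both genotypes.

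The change from day 9 to day 14 was first measured in control dogs. On chromosome 13, a gene from 33735489 to 33974004 rose from 0.255 CPM ± 0.173 to 43.6 CPM ± 38.1 (SD, n = 5 each), a log2 fold change of 7.36 ± 0.81 (edgeR adjusted p = 1.29e-06), which was 6.71 without control day 14 replicate 4. The gene on chromosome 7 from 19498755 to 19514228 was at least 94.2-fold higher at day 14 (46.4-fold with counts halved), with 0 counts over the 5 libraries of day 9; its fitted log2 fold change was 8.72, and 8.09 without control day 14 replicate 4. A gene on chromosome 2, from 70225456 to 70234420, fell from 1247 CPM ± 91.3 to 192 CPM ± 66.3, a log2 fold change of -2.70 ± 0.29. Likewise, a gene on chromosome 15 from 31670414 to 31735104 fell from 261 CPM ± 58.5 to 41.3 CPM ± 25.7, a log2 fold change of -2.66 ± 0.51. The most abundant gene of the data, on chromosome 27 from 6756994 to 6787846, took 31.9% ± 3.62 of all counts at day 9 and 17.5% ± 5.83 at day 14 (exact two-sided permutation p = 0.00794, adjusted p = 0.0397, n = 5 each). In affected dogs it took 25.6% ± 10.5 and 22.0% ± 4.25 (exact permutation p = 0.524, adjusted p = 0.6702).

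Runs of neighbouring genes changed at 52 places with age in controls, 40 higher and 12 lower, against 10.4 on average and 21 at most in reordered genes (permutation p = 0.001, the smallest possible). Here too some runs were short, such as 3 genes within 0.8 kb on chromosome 1 from 71677608. On chromosome 32 the 3 genes between 11051535 and 11362391 rose by 2.998 to 4.74 on the log2 scale, the middle one from 297 CPM ± 92.1 to 3055 CPM ± 1244. On chromosome 27, 8 genes between 35828941 and 36766777 rose by 1.47 to 2.80. On chromosome 18, 8 genes between 46124411 and 46324933 fell by 1.03 to 2.35; the most abundant of them, starting at 46293985, went from 1616 CPM ± 344 to 447 CPM ± 178. On chromosome 16, 6 genes between 14752828 and 14896569 rose by 1.71 to 2.49, and the 4 genes of the run on chromosome 9 rose by 1.34 to 2.68.

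With age in controls 6187 genes (42.5%) changed, 3176 higher and 3011 lower at day 14 (edgeR, adjusted p under 0.05). At least 2-fold changes were found in 1289 that rose and 639 that fell. Of the 20 most abundant genes 11 fell and 2 rose (median log2 fold change -0.62, camera adjusted p = 0.0127). That call was lost with an estimated correlation (adjusted p = 0.279 with an estimated correlation) and with the trend on exon length removed (adjusted p = 0.279). Genes with over 5000 bases of exon stood higher at day 14 than other genes, with 830 that rose and 390 that fell among 2473 (camera adjusted p = 5.68e-04; 0.00211 as the adjusted p with an estimated correlation). The median change rose with exon length, from -0.27 in genes of up to 1038 bases to 0.14 in genes of at least 4625 bases. The group of long genes is part of this trend and was not tested apart from it. Of 1184 single-exon genes 137 rose and 261 fell (median -0.32, camera adjusted p = 0.0613); the group passed the threshold under median-ratio scaling (adjusted p = 0.0405) and with an estimated correlation (adjusted p = 0.0421). The share of even counts, a property of the libraries described in the methods, fell from 74.9% ± 1.62 to 70.8% ± 1.84 over the same ages (exact permutation p = 0.00794, adjusted p = 0.0397, n = 5 each).

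In affected dogs the same ages were compared. Among them, a gene on chromosome 27 from 5411374 to 5412162 rose from 0.668 CPM ± 0.411 to 9.09 CPM ± 1.62 (SD, n = 5 each), a log2 fold change of 3.76 ± 0.31 (edgeR adjusted p = 5.92e-08), and by 4.32 ± 0.32 in controls. On chromosome 6, a short gene of 86 bases from 74881601 to 74881686 rose from 0.0898 CPM ± 0.0752 to 3.81 CPM ± 0.586, a log2 fold change of 5.35 ± 0.48, and by 4.07 ± 0.45 in controls. A gene on the unplaced scaffold JH373574.1, from 7225 to 25812, fell from 10.6 CPM ± 5.32 to 2.95 CPM ± 0.955, a log2 fold change of -1.85 ± 0.37. On chromosome 8, a gene from 50274583 to 50285876 had a log2 fold change of -1.82 ± 0.49 (edgeR adjusted p = 0.0116), which went to -0.95 (edgeR adjusted p = 0.0547) without affected day 9 replicate 3 and lost its call with only the affected libraries in the fit (edgeR adjusted p = 0.0591).

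Neighbouring genes changed together at 5 places in affected dogs, 4 higher and 1 lower, against 0.354 on average in reordered genes (permutation p = 0.001, the smallest possible). On chromosome 6, 3 genes between 68077795 and 68400785 rose by 1.45 to 2.02 on the log2 scale, and on chromosome 3, 3 genes between 73520706 and 73570744 rose by 1.49 to 1.64. On chromosome 21, 3 genes between 40627471 and 40704729 fell by 2.08 to 2.77. Another run on chromosome 21, from 7019136, held 3 genes within 1.7 kb, which need not be separate changes. The number of runs was 2 without affected day 9 replicate 1 or 5 or affected day 14 replicate 3, and 3 without affected day 9 replicate 4. In all, 3297 genes (22.7%) changed with age in affected dogs, 1854 higher and 1443 lower by the same edgeR test, and 428 rose and 167 fell at least 2-fold. With only the affected libraries in the fit 1466 passed, 1169 higher and 297 lower. Genes with over 5000 bases of exon again stood higher, with 617 that rose and 134 that fell (camera adjusted p = 3.05e-06; 1.41e-04 as the adjusted p with an estimated correlation), as part of the same trend.

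Genes that changed with age in controls mostly moved the same way in affected dogs, which shared no library with them. A batch or depth difference that went with age in both genotypes could also give a shared direction, and cannot be told apart from age here. Of the control genes 89.3% had the same sign, 86.8% of those that rose and 91.9% of those that fell. The fry test of limma, which asks whether a set moves on balance in a given direction, gave a p of 1.09e-07 for the risers and 2.07e-05 for the fallers. Both genotypes called 1472 genes higher and 864 lower, where independent lists would share 405 and 299, and 17 genes were called in opposite directions. To size the change without measuring genes in the libraries that picked them, genes were picked in 3 against 3 control libraries and measured in the held-out control libraries and in the affected ones, over 100 choices. Picked risers rose by 0.78 in held-out controls and 0.46 in affected dogs on the log2 scale (medians), a ratio of 0.602 (10th to 90th percentile of the choices 0.550 to 0.683). Picked fallers changed by -0.60 and -0.32, a ratio of 0.537 (0.472 to 0.626). All choices used the same affected libraries, so these percentiles hold no spread among affected dogs. The ratio was 0.686 for risers picked with a log2 change under 1, 0.509 for those of 1 to 2, and 0.376 for those over 2, whose medians were 2.06 in held-out controls and 0.78 in affected dogs. For fallers of the same sizes it was 0.565, 0.407 and 0.436, with no steady fall, and 0.626, 0.513 and 0.593 without affected day 9 replicate 3.

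**Figure D3:**
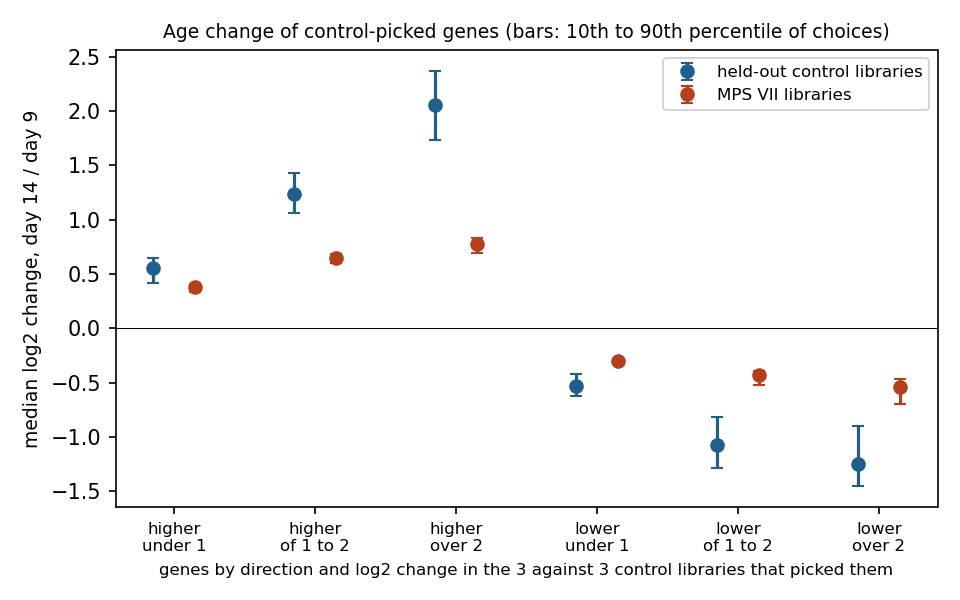
Median log2 change from day 9 to day 14 of genes picked in 3 against 3 control libraries, by direction and size of the change in those libraries, in held-out control libraries and in affected libraries; points are medians over 100 choices and bars run from the 10th to the 90th percentile. Risers picked with a change over 2 rose by 2.06 in held-out controls and 0.78 in affected dogs.

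The difference of the age change between genotypes was tested directly, by the interaction term. On chromosome 33, a gene from 785673 to 1092293 rose from 6.65 CPM ± 0.885 to 69.6 CPM ± 22.4 in controls and stood at 10.5 CPM ± 0.763 and 13.7 CPM ± 2.44 in affected dogs (SD, n = 5 each), a difference of -2.99 ± 0.25 on the log2 scale (edgeR adjusted p = 5.32e-07). A gene on chromosome 18, from 42616367 to 42665127, went from 9.64 CPM ± 1.57 to 42.6 CPM ± 13.0 in controls and stood at 7.54 CPM ± 0.675 and 6.397 CPM ± 1.19 in affected dogs, a difference of -2.37 ± 0.25. The gene on chromosome 13 from 33735489 stood at 0.606 CPM ± 0.656 and 0.210 CPM ± 0.177 in affected dogs, a difference of -8.93 ± 1.29 (edgeR adjusted p = 0.00120), which was -8.24 without control day 14 replicate 4. In the other direction, a gene on chromosome 18, from 32476290 to 32547935, fell from 93.5 CPM ± 11.1 to 28.3 CPM ± 5.97 in controls and stood at 105 CPM ± 11.5 and 77.3 CPM ± 16.3 in affected dogs, a difference of 1.28 ± 0.21 (edgeR adjusted p = 0.00303). A gene on chromosome 26, from 7896837 to 7914234, fell from 33.6 CPM ± 2.92 to 22.3 CPM ± 2.39 in controls and stood at 39.5 CPM ± 2.50 and 46.1 CPM ± 4.31 in affected dogs, a difference of 0.82 ± 0.13.

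The age change differed in 474 genes (edgeR, adjusted p under 0.05), 354 more negative and 120 more positive in affected dogs. Of the 354, 345 rose with age in controls, and of those 271 were not called in affected dogs, 61 rose less and 13 fell. Of the 120, 112 fell with age in controls, and of those 96 were not called in affected dogs, 12 fell less and 4 rose. Since the interaction subtracts the control change, a gene with a strong control change is more easily called. The held-out ratios measure controls in libraries that did not pick the genes, but their genes too were picked by the control change. The only run of neighbouring genes was that on chromosome 32 between 11051535 and 11362391, whose 3 genes differed by -6.77 to -2.47 (1 run against 0.046 on average in reordered genes, permutation p = 0.046), and 2 runs were found without affected day 9 replicate 3 or 4. The count of 474 varied from 199 without control day 14 replicate 4 to 759 without affected day 9 replicate 3 when libraries were left out in turn, and was 926 with DESeq2 and 879 with 1 surrogate variable. X-chromosomal genes stood higher as a group in this comparison (median 0.10, 7 called higher and 9 lower of 555, camera adjusted p = 0.0158), a call lost with an estimated correlation (adjusted p = 0.0691 with an estimated correlation). Since sex was not used, the mix of sexes in the groups cannot be told apart from the difference here. The 20 most abundant genes also stood higher (median 0.43, 0 called higher and 1 lower, camera adjusted p = 0.00786; adjusted p = 0.219 with an estimated correlation, and 0.0799 with the trend on exon length removed). In affected day 9 replicate 3, 10 of the 20 lay below the rest of its group, and without that library the adjusted p was 0.0290. For genes under 300 bases of exon the camera adjusted p was 0.0332 (median 0.14, 3 called higher and 3 lower of 392), and 0.219 as the adjusted p with an estimated correlation; it was 0.204 without affected day 9 replicate 3.

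**Figure D4:**
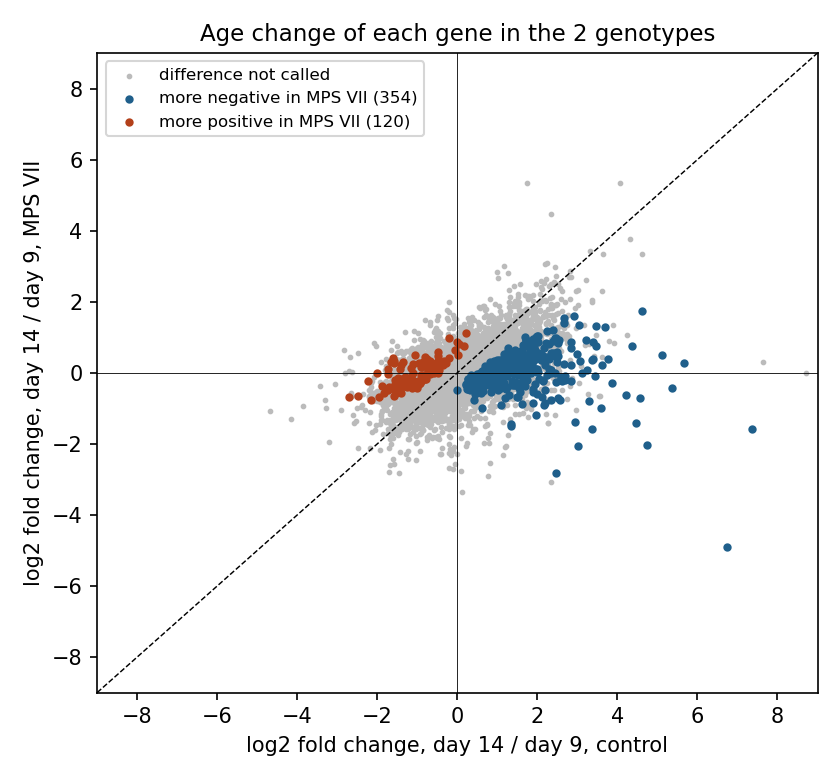
Fitted log2 fold change from day 9 to day 14 of each tested gene in control dogs (x axis) and affected dogs (y axis); coloured points are the 354 genes whose change was more negative and the 120 whose change was more positive in affected dogs, and the dashed line marks equal change. Fitted values of genes with 0 counts in a group depend on the prior count.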

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

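The tests of the 3 patterns weighed here were chosen after the patterns were seen, and what each test would show was written before its result, except for the tests of the 20 most abundant genes and of the fallers by size, written after. The rule for single libraries far from their group compared the gap to the nearest library with the range of the group, in 88 sets of 5 libraries. It marked 8, where chance would mark 4.4. Of the 8, 5 were in affected day 9 replicate 3. Its 20 most abundant genes took 23.3% of counts against 43.0% to 51.0% in the rest of its group. The gene ENSCAFG00000002753 stood at 423.7 CPM there (246.7 to 286.4 in the others), ENSCAFG00000019945 at 297.9 CPM (14.9 to 28.7), the gene on chromosome 8 from 50274583 at 11.9 CPM (1.93 to 3.103), and the gene on chromosome 26 from 7896837 at 35.0 CPM (40.0 to 41.0). The share of even low counts was 71.2% in affected day 9 replicate 1 against 75.1% to 76.4% in its group. In control day 9 replicate 4, ENSCAFG00000015404 stood at 0.696 CPM (2.77 to 4.23) and the gene on chromosome 18 from 42616367 at 6.96 CPM (9.73 to 10.97).

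Affected day 9 replicate 3 had 49 genes more than 4-fold above and 74 more than 4-fold below all other libraries. A swapped genotype is argued against. It was judged on 384 genes called for genotype the same way at both ages without this library, at least 2-fold at day 9. On these, the median position of this library was 1.09 on a scale from control (0) to affected (1). The other affected day 9 libraries, which helped to pick the genes, lay at 0.864 to 1.10. A wrong age is argued against too. It was judged on 529 genes called with age the same way in both genotypes without this library, at least 2-fold in affected dogs. On these, its position between day 9 (0) and day 14 (1) was 0.173, near the others at -0.0980 to 0.135. The low share of the 20 most abundant genes could not account for it through scaling either, since the counts left to other genes would raise them at most 1.61-fold against any other library, and 74 genes lay lower. A different mix of tissue in the sample, and a difference of this animal, stay open, because no marker gene could be named here.

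The age change of genes followed their exon length in both genotypes, with a gap between genes of at least 4625 and of up to 1038 bases of 0.40 in controls and 0.34 in affected dogs on the log2 scale. When every library was thinned to 15772761 counts, 98.1% of the gap remained in affected dogs and 99.8% in controls. This argues against a direct effect of the lower number of counts at day 14 on the fit. Thinning keeps the expected share of each gene, so it cannot speak to library differences that went with depth. A difference between library batches or in RNA quality may contribute, but no label ties the share of even low counts to either. Within groups, the slope of log2 CPM on log2 exon length went with that share (20 libraries, Pearson r = -0.694, permutation p = 6.0e-05). The Spearman rho was -0.820 (permutation p = 1.2e-04), and r was -0.747 without the 2 libraries farthest from the median. Both measures come from the same counts, so this link alone does not point to a batch or to RNA quality. The length trend was not the whole cause of the age calls, since 84.2% of the genes called in controls kept their call and direction with the trend removed (75.5% in affected dogs). Each age holds its own libraries and no batch is given, so a batch and a true change with age cannot be told apart. This holds for the trend, for all genes called with age in either genotype, and for the direction that both genotypes shared.

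The age change of controls was smaller in affected dogs. Picking genes in the libraries that measure them is argued against as the cause, since the ratio to held-out controls was 0.602 for risers, with a 90th percentile of 0.683. Genes were picked in controls only, never in affected dogs, so a general damping of age changes in affected dogs is not shown. A single delay that scales the change of every riser by the same factor is argued against as well. The ratio for strong risers was 0.536 times that for weak risers (0.464 to 0.645 over 100 choices). All choices used the same affected libraries, so these ranges hold no spread among affected dogs. An average scaling around which genes differ stays open, since the risers were picked by the control change alone. For fallers a scaling by the same factor stays open too. The same quotient was 0.751, with 0.379 to 2.41 over the choices (median 0.916 without affected day 9 replicate 3). With only 2 ages, a delay in time that takes a larger share from steep risers was not tested and stays open. A smaller response of some genes in affected dogs stays a hypothesis, found and tested in the same libraries, with ratios of 0.637 for risers and 0.609 for fallers without affected day 9 replicate 3.

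The age change differed between genotypes, by the interaction term of the edgeR fit, in 8 of the genes described and in 3.26% of all tested genes. Of the 8, 4 on chromosomes 26, 33 and 18 were chosen for this term. The others, on chromosomes 5, 4, 13 and 2, were chosen for large changes with genotype at day 14 or with age in controls. Those changes are part of the interaction term, so the share among the described genes cannot be weighed against the share of all genes. The differences, affected minus control on the log2 scale, were 1.86 for the gene on chromosome 5 from 55782140, -11.64 for that on chromosome 4 from 57934459, -8.93 for that on chromosome 13 from 33735489, 2.02 for that on chromosome 2 from 70225456, 0.82 for that on chromosome 26 from 7896837, 1.28 for that on chromosome 18 from 32476290, -2.99 for that on chromosome 33 from 785673, and -2.37 for that on chromosome 18 from 42616367. The value on chromosome 4 is a fitted one with 0 counts in all affected day 14 libraries, so it depends on the prior count and is no bound; it was -12.73 without control day 9 replicate 3, which held 4 of the 6 counts of its group. The call on chromosome 5 (edgeR adjusted p = 0.0493) was lost with median-ratio scaling, with no filter, with halved counts and without most of the libraries, left out in turn (edgeR adjusted p 0.0501 to 0.108).

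For each of the 5 comparisons, 100 splits of the libraries into groups of the same sizes were drawn and fitted, the real one among them. Only the real split gave as many genes. For genotype at each age and for age in each genotype this argues against chance but does not exclude it, since not all splits were drawn. For the difference, genotype labels were shuffled within each age. Such splits can carry the genotype change itself into the difference, so they cannot decide about chance there. Splits that mix groups that differ also widen the spread within groups, which lowers their counts. The real count and the highest other were 1220 and 62 for genotype at day 9, 3202 and 243 for genotype at day 14, 6187 and 6 for age in controls, 3297 and 2762 for age in affected dogs, and 474 and 301 for the difference. The 301 came from 1 split, the next gave 58, so the highest other depends on which splits were drawn. That split exchanged 12 libraries, among them control day 9 replicates 1 to 4 and affected day 9 replicates 1, 3, 4 and 5. The split with 2762 genes exchanged affected day 9 replicate 3 with affected day 14 replicate 1, and with it 6 splits other than the real one called more than 100 genes in that comparison. Each of the 6 exchanged only 1 library of each age, so 8 of the 10 libraries kept their age in them.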

How the results depend on the processing

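No paired analysis was made, because replicate numbers were given in the order of the samples and no litter was used here. The fits therefore leave out the stated matching of litters between genotypes. The tests with halved counts, with the exon length trend removed, of the gene groups and runs, and of the held-out ratios without a library were chosen after the data were seen. Of the recomputed counts, shares, correlations and ratios 172 stayed within their limits and 18 did not. For a count of changed genes the limit covered its total, not its balance of higher and lower genes. With the trend on exon length removed, 1548 genes were higher and 1690 lower in affected dogs at day 14, against 1640 and 1562 in the main fit. With only the groups compared, 711 genes passed for genotype at day 9 and 1466 for age in affected dogs, where fewer samples entered the fit; this setting was not run for the difference. With a 2-fold threshold 608, 1217, 1928, 595 and 283 genes passed in the 5 comparisons, since fewer changes qualify. For the difference of the age change, DESeq2 called 926 genes and the fit with 1 surrogate variable 879, against 474; the cause was not tested. Leaving out each library in turn gave 896 to 1448 genes for genotype at day 9, 2448 to 3312 for genotype at day 14, 5186 to 5911 for age in controls, 2227 to 3902 for age in affected dogs, 570 to 767 genes called for genotype at both ages, shares of 87.9% to 90.8% and correlations of 0.490 to 0.590. For the difference it gave 199 to 759, and 8 of 20 libraries moved it by over 1.5 times: 248, 308, 276 and 263 genes without control day 9 replicate 2, 3, 4 and 5, 224 and 199 without control day 14 replicate 1 and 4, 253 without affected day 14 replicate 5, and 759 without affected day 9 replicate 3, the cause of which was not tested. The ratio for fallers moved to 0.609 without that library. For genes under 300 bases of exon, the direction of the difference reversed with the length trend removed (camera adjusted p = 0.998), a correction that acts on the length by which they were grouped. Over the genes described, 52 called values were recomputed under 1104 alternatives; 1058 kept call and direction, 46 lost the call and 0 reversed. Other scalings shifted the median fold change by -0.051 to 0.047 on the log2 scale. The planned settings of the gene lists and of GUSB were not run. At this depth genes with 0 counts allow only bounds.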

Other observations

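All values here were chosen after the data were seen. On chromosome 18, 3 short overlapping or adjacent genes between 46206173 and 46207250 were higher in affected dogs at day 14 by 1.42 to 1.66 on the log2 scale, within the region where 8 genes fell with age in controls. They stood at 39.5 CPM ± 11.9, 55.4 CPM ± 15.8 and 59.6 CPM ± 13.5 in control dogs of day 14, and at 110 CPM ± 34.4, 176 CPM ± 81.4 and 159 CPM ± 34.7 in affected dogs (SD, n = 5 each). At day 9 the genotypes did not differ by the edgeR test at any of these 3 genes (log2 fold changes -0.07, -0.09 and -0.09). On chromosome 27, the gene starting at 36654072 stood at 11.02 CPM ± 3.53 and 43.6 CPM ± 18.8 in control and affected dogs of day 9 and at 33.3 CPM ± 7.35 and 63.2 CPM ± 21.2 at day 14, and so was higher in affected dogs at both ages (log2 fold changes 1.99 ± 0.29 and 0.92 ± 0.28, edgeR adjusted p = 1.34e-04 and 0.0224), while its neighbour starting at 35828941 was lower in affected dogs at day 14 (-1.41 ± 0.29, edgeR adjusted p = 0.00105).

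A feature of 126 bases on the X chromosome, from 57332501 to 57332626, held 355 to 778 counts in 11 libraries and 0 in 9. A feature of the same length on chromosome 26, from 28255924 to 28256049, held 137 to 313 counts in those 9 libraries and at most 2 in the 11. The 11 libraries were 2 control and 4 affected of day 9, and 3 control and 2 affected of day 14. Libraries were not grouped by these features.

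Genes called for genotype the same way at both ages were counted per chromosome. Chromosome 4 held 35 among 409 tested genes (8.56% against 4.94% over all), with a Fisher's exact p of 0.00159, which failed the adjustment over 39 chromosomes (adjusted p = 0.0621).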
